A study of Homo sapiens with 6 samples.

How the data were processed

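RNA was measured on Affymetrix U133 Plus 2 expression arrays in PHM1-31 cells, an immortalised human smooth muscle cell line from the myometrium, the muscle layer of the womb. The 6 arrays fall into 2 groups of 3, named in the array titles: cells stimulated with tumour necrosis factor (TNF) at 10 ng/ml for 1 h, and cells left unstimulated for the same time. Per the labels' protocols, total RNA was extracted with Tri-reagent, treated with DNase and checked on a Bioanalyzer, and biotinylated aRNA was hybridised. The labels do not say whether replicates came from separate cultures, so p-values here measure the spread between these samples, which may be technical. The labels name no vehicle-treated or mock-handled flasks.

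The values used are the authors' deposited log2 probe-set values, one per probe set and array. Per the submitters' processing notes, the data were analysed in Partek 6.6. The background correction, the normalization and the summarization of probes are not given in the sources used here, and the log base was inferred from the range of the values, 1.83 to 14.17. The 6 arrays had medians of 5.47 to 5.53, and equally ranked values lay within 0.081 of their mean over arrays, so the deposited arrays have nearly the same distribution. Such a normalization removes any change that shifts most genes in one direction. Between any 2 arrays at most 0.483% of probe sets had identical values, and Pearson correlations over all probe sets ran from 0.9943 to 0.997, so no array was a copy of another. Arrays carry no read depth, and the number of arrays limits the precision. No detection calls were used, so a low value is not shown to be above background. Changes of called named genes whose lower group mean lay below the lower quartile of gene levels, 5.08, are marked as possibly understated, a choice made after seeing the data. They keep their sampling error.

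Of 54675 probe sets, 62 were control probe sets and 41091 paired with exactly 1 gene symbol in the platform annotation. Another 1801 paired with several genes, and 11721 had no gene in the table used and are unnamed here. Gene identifiers of 41037 single-gene probe sets were found in the current RefSeq gene table, and no symbol differed from it. Each of the 19775 genes was represented by the probe set with the highest mean over all 6 arrays. Of these genes 10523 had more than 1 probe set, and disagreement among them is given for named genes that were called.

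Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, no filter on level), on the log2 scale, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Errors of fold changes are limma's moderated standard errors, group values are means ± SD of 3 arrays, and intervals are 95% intervals. There were 19 gene lists, each tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 19 lists, and again with an estimated correlation and with fry. The array control probe sets were compared by an exact permutation test, which cannot go below 0.1 for 3 arrays against 3.

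The samples' groups, the main design, the gene lists, 14 alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, up to 4 called members of each list (or the 2 with the largest change where none was called), and 13 genes fixed by name. It gave 68 genes, 1 of which is not reported here. The alternatives were a replicate block, other moderation of the variance, no moderation, quantile normalization, median centring, a filter on level, 3 other treatments of probe sets, array weights, leaving out each array in turn, and for lists an estimated correlation and fry. An RNA-quality covariate, lists without their called members and list counts without TNF replicate 3 were added after seeing the data.

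The fit was tested on simulated data with the real genes' levels and spreads, for 3 TNF against 3 unstimulated arrays and 19775 genes. It recovered 64.2% of 67 genes changed by 0.6 on the log2 scale, 92.5% of 67 changed by 1 and 100% of 66 changed by 2, and 3.4% of its calls were false. In the list step the 1 shifted list was called and 0 of 20 unchanged lists were. The simulated genes varied independently, while estimated correlations in the real lists reached 0.237. The list step therefore does not test camera where the members of a list vary together. Plots were drawn with matplotlib 3.10.9. The promoter arrays of the wider study were not analysed here.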

Results

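Expression was profiled in PHM1-31 cells, an immortalised myometrial smooth muscle line, after 1 h with 10 ng/ml TNF and in unstimulated cells. TNF is an inflammatory cytokine whose receptors activate the transcription factor NF-kB. Each group had 3 arrays, and the 19775 genes tested had mean log2 values with a median of 6.58 and quartiles of 5.08 and 8.49. The series pairs these arrays with a study of promoter binding by RelA, an NF-kB subunit, and the comparison here asks which transcripts changed within 1 h of TNF.

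In the ACTB, 18S and M27830 5' control measurements the groups did not overlap. The M27830 5' control was at 12.73 to 12.79 (log2) in unstimulated arrays and 12.54 to 12.61 in TNF arrays, and was not tested. TNF replicate 3 was the highest TNF array there. The 3' minus 5' difference of the ACTB control probe sets, which widens when RNA is degraded or labelled incompletely, was 0.81 ± 0.15 (SD, n = 3) on the log2 scale in unstimulated arrays and 1.52 ± 0.86 (SD, n = 3) in TNF arrays. TNF replicate 3 had 2.52, against 1.02 and 1.03 in the other TNF arrays and 0.65 to 0.95 in the unstimulated arrays. All 3 TNF arrays lay above all 3 unstimulated arrays, which gave the smallest p this design allows (exact permutation test, two-sided, p = 0.1). The GAPDH difference was 0.03 ± 0.03 in unstimulated and 0.09 ± 0.05 in TNF arrays (exact permutation test, p = 0.2). Control probe sets for 18S ribosomal RNA were at 13.14 ± 0.05 in unstimulated and 12.76 ± 0.35 in TNF arrays, with TNF replicate 3 at 12.35 (exact permutation test, p = 0.1). The main counts below are therefore also given without TNF replicate 3.

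**Figure D1:**
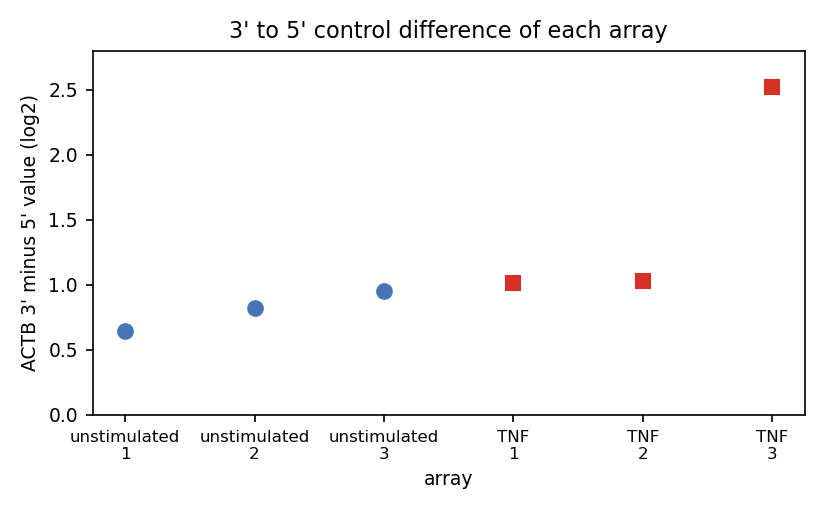
The 3' minus 5' difference of the ACTB control probe sets (log2, y axis) for each of the 6 arrays (x axis), with circles for unstimulated and squares for TNF arrays. TNF replicate 3 sits at 2.52 and the other arrays between 0.65 and 1.03.

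After 1 h of TNF, 102 genes were higher and 13 were lower. The largest rises were in genes for inducible transcription factors. EGR3 (gene ID 1960) rose 32.3-fold, a value that background signal may make too low. FOSB (2354) rose 15.8-fold, FOS (2353) 13.7-fold and EGR1 (1958) 13.2-fold. TNFAIP3, which encodes the ubiquitin-editing inhibitor A20 that limits NF-kB activation, rose 7.55-fold. The cytokine IL6 rose 3.07-fold, and PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, rose 3.45-fold. The largest fall was in ID1, an inhibitor of basic helix-loop-helix transcription factors, which fell by 0.92 on the log2 scale. In all 115 called genes the 3 TNF values lay on one side of the 3 unstimulated values, as they did in 11.6% of all genes, where chance gives 10%. At least 1.5-fold, 78 genes were higher and 6 were lower, and 40 genes were higher by 2-fold or more while 0 were measured as lower by as much. limma's test called these genes at an adjusted p under 0.05, and 1444 of the 19775 genes tested had an unadjusted p under 0.05. Chance alone gives such an unadjusted p in a share of 0.05 of unchanged genes. Without TNF replicate 3, 101 genes were called, 93 of them shared with the full comparison. Without unstimulated replicate 3, 75 genes were called, all of them among the 115.

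**Figure D2:**
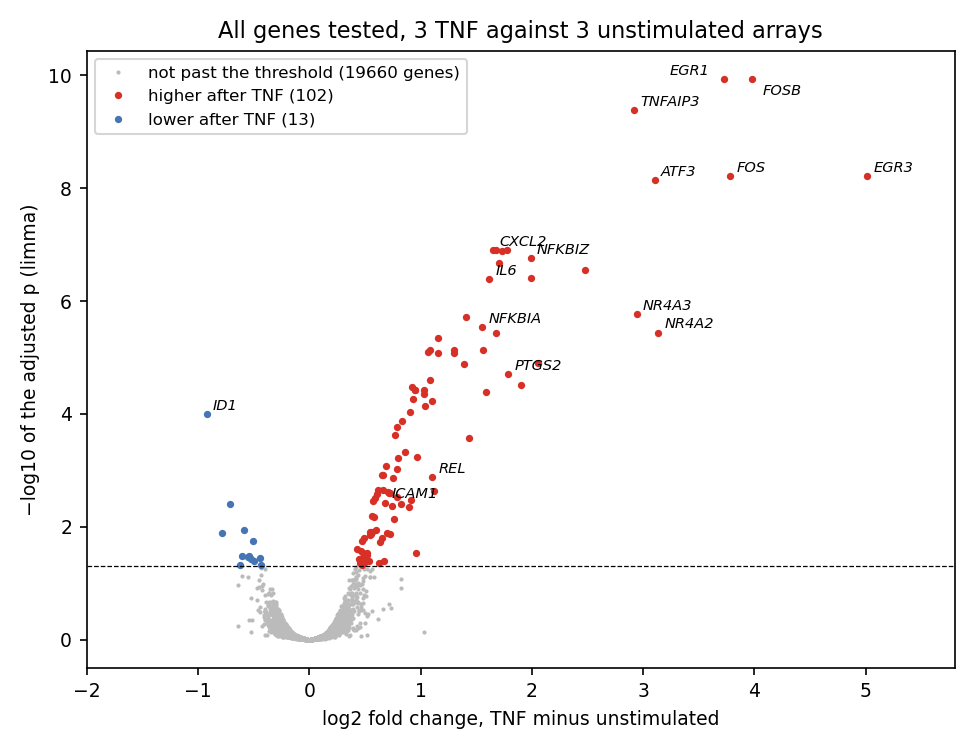
Each point is 1 of 19775 genes, with the log2 fold change of TNF minus unstimulated on the x axis and −log10 of limma's adjusted p on the y axis. The dashed line marks an adjusted p of 0.05, and 102 red points lie to the right and 13 blue points to the left, with EGR3 at 5.01 and ID1 at -0.92.

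Immediate-early and serum response genes were the group with the most called members, 27 of 52 measured members higher and 1 lower. Among the genes tested, the 10 largest rises were EGR3, FOSB, FOS, EGR1, NR4A2, ATF3, NR4A3, TNFAIP3, DUSP2 and TCIM, and 8 of these 10 belong to this list. A probe set with no gene in the table used rose by 2.72, and it stands outside this ranking. EGR2, BTG2 and MAFK, also on the list, were not tested, since in the table used no probe set paired with any of them alone. Their probe sets may lie among those with several genes or with no gene, so a lack of change is not shown. EGR3 rose from 3.59 ± 0.14 to 8.61 ± 0.50 (log2, SD, n = 3), a log2 fold change of 5.01 (SE 0.18). This change may be understated, since the unstimulated value is not shown to be above background. FOSB rose by 3.98 ± 0.10 and FOS by 3.78 ± 0.14, both members of the AP-1 family. EGR1 rose by 3.73 ± 0.09, and its 3 probe sets gave 3.49 to 3.85. The nuclear receptors NR4A2 and NR4A3 rose by 3.13 ± 0.22 and 2.94 ± 0.19. The stress-inducible factor ATF3 rose by 3.11 ± 0.12, and its other probe sets gave 1.16 and 0.01. NR4A3 had 1.99 and -0.14 at its other probe sets. DUSP2, a phosphatase of MAP kinases, rose by 2.48 ± 0.13. TCIM, outside the lists, rose by 2.05 (SE 0.16), which may be understated, again from a low unstimulated value of 4.96. The called member that fell was ID1, with a log2 fold change of -0.92 ± 0.09. Adjusted over the list alone, 35 members were higher and 2 lower. The list's mean log2 fold change was 1.00 and its median 0.70, with a camera adjusted p of 9.52e-67, and with an estimated correlation the adjusted p was 0.00864. Without TNF replicate 3, 27 members were again higher and 1 lower.

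**Figure D3:**
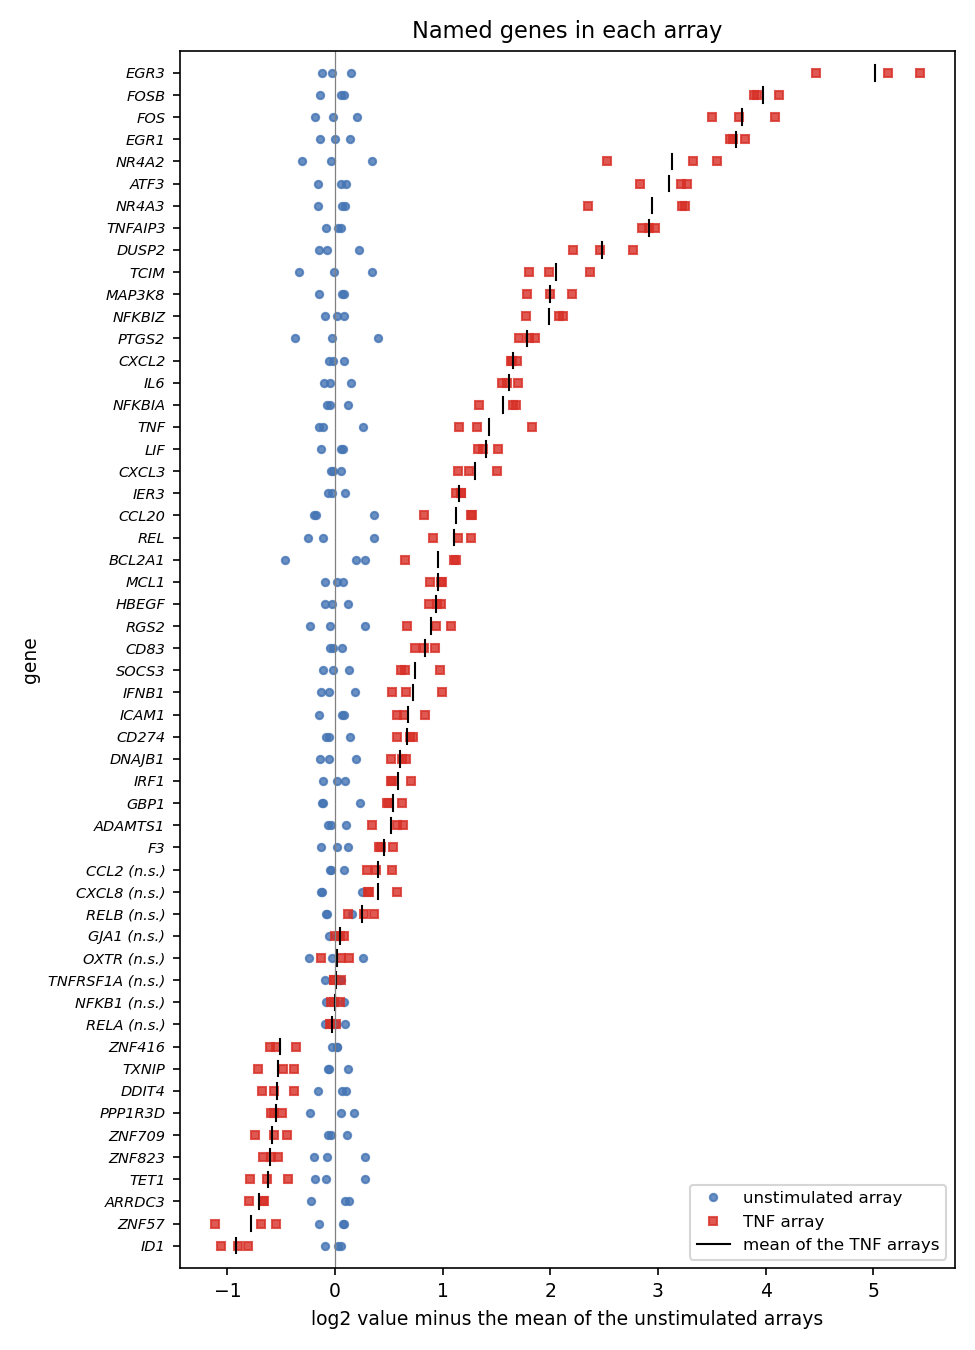
Log2 value of each array minus the mean of the unstimulated arrays (x axis) for named genes (y axis), with blue circles for unstimulated arrays, red squares for TNF arrays and a black bar at the TNF mean. Genes marked n.s. did not pass an adjusted p of 0.05. In called genes, from EGR3 at 5.01 to ID1 at -0.92, the 2 groups do not overlap.

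Inhibitors and feedback regulators of NF-kB had 5 of 17 measured members higher and 0 lower. TNFAIP3 rose by 2.92 ± 0.08 (SE, adjusted p = 4.21e-10, limma), and its second probe set gave 2.99. NFKBIZ, an atypical nuclear IkB protein, rose by 1.99 ± 0.10. NFKBIA, which encodes the inhibitor IkB-alpha, rose by 1.56 ± 0.11, from 10.87 ± 0.11 to 12.43 ± 0.19 (SD, n = 3). Its dim second probe set gave 0.25. SOCS3, a suppressor of cytokine signalling, rose by 0.75 ± 0.11, but missed the threshold without unstimulated replicate 1 (adjusted p = 0.064, limma) or unstimulated replicate 3 (0.0528). Its other probe sets gave 0.04 to 0.41. There were 8 higher members adjusted over the list alone. The camera adjusted p was 2.71e-15, and with an estimated correlation the adjusted p was 0.0215. The list's mean log2 fold change was 0.56 and its median 0.15. Without TNF replicate 3, 5 members were higher.

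The genes for the NF-kB subunits and their kinases had 1 of 10 measured members higher, also when adjusted over the list alone. That member was REL, which encodes c-Rel and rose by 1.10 ± 0.14 (SE), with its 5 probe sets between 0.44 and 1.44. RELA had a log2 fold change of -0.03 (95% interval -0.21 to 0.16), NFKB1 one of 0.00 (-0.18 to 0.18) and RELB one of 0.25 (0.04 to 0.46), with adjusted p of 0.978, 1.00 and 0.578 (limma). The list as a whole did not pass, with a camera adjusted p of 0.066. It passed without unstimulated replicate 1 (adjusted p = 0.019) and without TNF replicate 3 (adjusted p = 0.0366), with 1 member called in the latter. Among TNF receptors and proximal signalling genes, 1 of 17 measured members was higher. That member was MAP3K8, a kinase that activates the ERK pathway, which rose by 1.99 ± 0.11, with 0.27 at its dimmer probe set. The receptor gene TNFRSF1A had a log2 fold change of 0.01 (-0.17 to 0.19). This list had a mean of 0.11, a median of -0.02 and a camera adjusted p of 0.688, and 2 members were higher adjusted over the list alone.

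Cytokines and growth factors had 7 of 26 measured members higher, and chemokines had 3 of 17, with 0 lower in either list. IL6 rose by 1.62 ± 0.09 (SE), from 11.05 ± 0.13 to 12.67 ± 0.07 (SD, n = 3). TNF itself rose by 1.43 ± 0.16 and LIF, an IL6-family cytokine, by 1.40 ± 0.09. HBEGF, a ligand of the EGF receptor, rose by 0.93 ± 0.09, and its other probe sets gave 0.83, -0.07 and -0.01. Among chemokines, CXCL2 rose by 1.65 ± 0.08 and CXCL3 by 1.30 ± 0.10, both neutrophil attractants, and CCL20 by 1.12 ± 0.15. The other 2 probe sets of CXCL2, both dim, gave 0.31 and 0.15. CXCL2 lost its call when probe sets ending in _x_at or _s_at were left out, since its tested probe set ends in _x_at. CXCL8 and CCL2, attractants of neutrophils and monocytes, had log2 fold changes of 0.40 ± 0.12 and 0.40 ± 0.09 with adjusted p of 0.308 and 0.0888 (limma). With trended moderation both passed, at adjusted p of 0.0365 and 0.00093, and CCL2 also passed with trended robust moderation (0.000385) and with the filter on level (0.0274). They already stood at 12.71 ± 0.21 and 12.57 ± 0.08 (SD, n = 3) in unstimulated cells. Adjusted over the list alone, 13 cytokine genes were higher, and 7 chemokine genes were higher and 2 lower. Camera gave adjusted p of 4.39e-16 for cytokines and 8.98e-07 for chemokines. With an estimated correlation neither list passed, at an adjusted p of 0.0532 for cytokines and an adjusted p of 0.131 for chemokines. Without TNF replicate 3 the counts were 7 and 3, but the 7 were not all the same genes. TNFSF15, called in the full comparison, was not called there (adjusted p = 0.159, limma).

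Survival and apoptosis regulators had 3 of 13 measured members higher. IER3, an early response gene linked to cell survival, rose by 1.15 ± 0.08 (SE). MCL1 rose by 0.95 ± 0.08 and BCL2A1 by 0.96 ± 0.18, both anti-apoptotic relatives of BCL2. The 6 probe sets of MCL1 gave 0.04 to 1.02. BCL2A1 missed the threshold without unstimulated replicate 1 (adjusted p = 0.106, limma), unstimulated replicate 3 (0.102), TNF replicate 2 (0.0525) or TNF replicate 3 (0.0736). The list passed by camera (adjusted p = 1.27e-07) and with an estimated correlation (adjusted p = 0.0486). Adjusted over the list alone, 3 members were higher. Without TNF replicate 3 over all genes 3 were higher, but BCL2A1 was not among them.

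Adhesion molecules and inflammatory receptors had 4 of 24 measured members higher. CD83, an activation marker of antigen-presenting cells, rose by 0.83 ± 0.08 (SE). ICAM1, a leukocyte adhesion molecule, rose by 0.68 ± 0.10, with 0.36 and 0.08 at its other probe sets. CD274, which encodes PD-L1, rose by 0.67 ± 0.09, with 0.26 at its other probe set. F3, which encodes tissue factor, rose by 0.46 ± 0.09 and missed the threshold whichever array was left out (adjusted p from 0.0578 to 0.297, limma). Without unstimulated replicate 1 its adjusted p was 0.297, without unstimulated replicate 2 it was 0.104, and without unstimulated replicate 3 it was 0.0578. Without TNF replicates 1, 2 and 3 it was 0.173, 0.0754 and 0.1. The count was 5 higher adjusted over the list alone. The list passed by camera (adjusted p = 5.29e-06) but not with an estimated correlation (adjusted p = 0.075). Without TNF replicate 3, 3 members were higher.

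Labour and prostaglandin genes had 2 of 27 measured members higher. PTGS2 rose by 1.79 ± 0.15 (SE), from 8.89 ± 0.38 to 10.68 ± 0.07 (SD, n = 3), and its second probe set gave 1.66. RGS2, a regulator of G protein signalling, rose by 0.89 ± 0.13, but missed the threshold without unstimulated replicate 1 (adjusted p = 0.0563, limma) or unstimulated replicate 3 (0.0683). OXTR, the oxytocin receptor, had a log2 fold change of 0.02 (95% interval -0.24 to 0.28), and GJA1, the gap junction protein connexin 43, one of 0.04 (-0.13 to 0.22). The list did not pass by camera (adjusted p = 0.361), with 3 members higher adjusted over the list alone and 2 higher without TNF replicate 3. Of the smooth muscle contractile genes 0 of 24 passed, also adjusted over the list alone, with a mean log2 fold change of 0.07 and a camera adjusted p of 0.0708. The list passed without TNF replicate 1 (adjusted p = 0.0472), with a mean of 0.09. The transcriptional coactivator MYOCD had a log2 fold change of 0.27 ± 0.14 (SE).

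Interferon response genes had 3 of 32 measured members higher. IFNB1, which encodes interferon-beta, rose by 0.73 (SE 0.12), which may be understated, from a low level of 4.69 ± 0.16 (SD, n = 3). The transcription factor IRF1 rose by 0.58 ± 0.09, and GBP1, a guanylate-binding protein, by 0.53 ± 0.10. Of the other GBP1 probe sets 2 gave 0.49 and the dimmest gave -0.03. IFNB1 missed the threshold without unstimulated replicate 1 (adjusted p = 0.16, limma) or unstimulated replicate 2 (0.0655), and IRF1 without unstimulated replicate 3 (0.0538). GBP1 missed it without unstimulated replicate 1 (0.319), unstimulated replicate 2 (0.145), TNF replicate 1 (0.147), TNF replicate 2 (0.0583) or TNF replicate 3 (0.0785). The list as a whole had a mean log2 fold change of -0.03 and a median of -0.08, and camera gave it a downward direction with an adjusted p of 0.0139. With an estimated correlation that call was lost (adjusted p = 0.352), and it was lost without TNF replicate 1 (adjusted p = 0.204). Adjusted over the list alone, 3 members were higher and 1 lower, and without TNF replicate 3 over all genes 2 were higher.

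Matrix and protease genes had 1 of 25 measured members higher. That was the protease gene ADAMTS1, which rose by 0.52 ± 0.10 (SE), with 0.14 at its dimmer probe set. It missed the threshold without unstimulated replicate 1 (adjusted p = 0.251, limma), unstimulated replicate 3 (0.178), TNF replicate 2 (0.107) or TNF replicate 3 (0.111), so that 0 members were called without TNF replicate 3. There were 3 higher members adjusted over the list alone. The list passed by camera (adjusted p = 0.0152, mean log2 fold change 0.10), but not with an estimated correlation (adjusted p = 0.131), without unstimulated replicate 1 (adjusted p = 0.0609) or without TNF replicate 1 (adjusted p = 0.1). Heat shock and stress genes had 1 of 22 measured members higher and 1 lower, and the list did not pass (camera adjusted p = 0.969). The same counts held adjusted over the list alone and without TNF replicate 3. The chaperone gene DNAJB1 rose by 0.60 ± 0.10, with 0.28 at its dimmer probe set, and missed the threshold without unstimulated replicate 2 (adjusted p = 0.057) or unstimulated replicate 3 (0.0806).

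**Figure D4:**
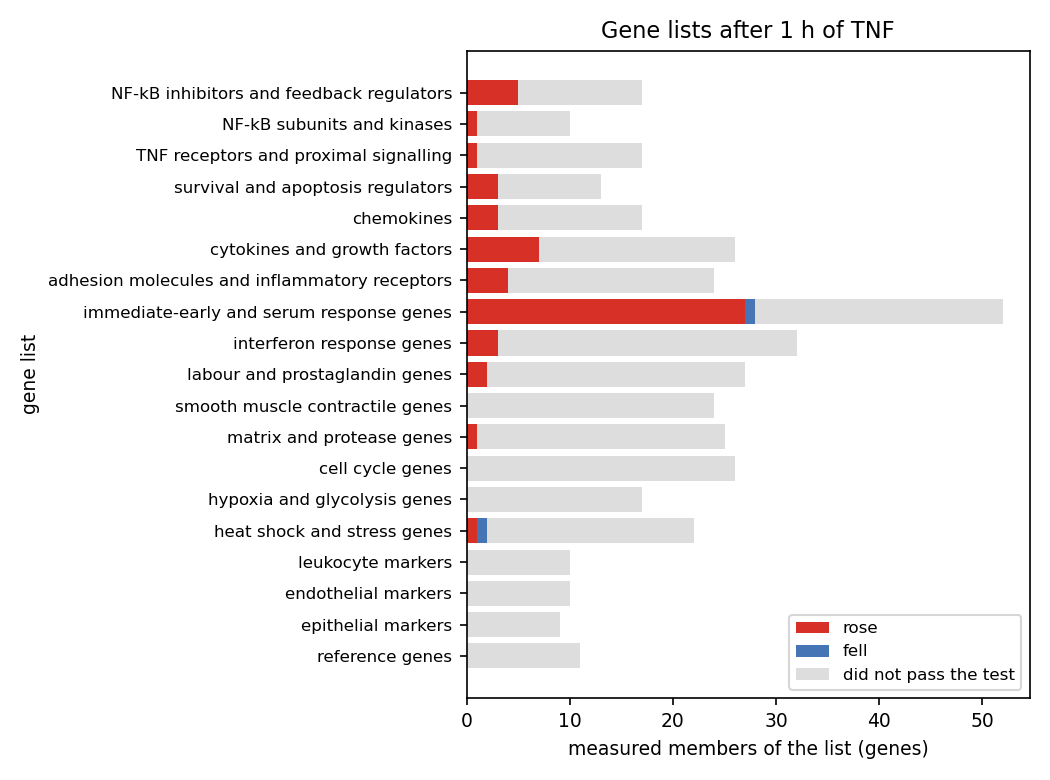
Number of measured members (x axis) of each of the 19 gene lists (y axis) that rose (red), fell (blue) or did not pass an adjusted p of 0.05 (grey). The immediate-early list has 27 rises among 52 members, and the contractile, cell cycle, hypoxia, marker and reference lists have 0 calls.

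In the remaining lists 0 members passed limma's test over all genes, adjusted over the list alone or without TNF replicate 3. The lists covered 26 cell cycle, 17 hypoxia and glycolysis and 11 reference genes. They also covered 10 leukocyte, 10 endothelial and 9 epithelial markers. A lack of called changes in these markers does not show that such cells were absent. Purity was not tested, and the highest unstimulated mean in the epithelial list was 10.83, in KRT19. The camera adjusted p of the lists, in the order named, were 0.783, 0.361, 0.439, 0.0959, 0.969 and 0.969. The leukocyte list passed without unstimulated replicate 3 (adjusted p = 0.0355). The 2 largest changes per list were -0.20 in AURKB and -0.15 in CDC20, -0.54 in VLDLR and 0.32 in PFKFB4, and -0.11 in YWHAZ and -0.07 in TBP. In the marker lists they were 0.27 in PTPRC and 0.21 in LYZ, -0.19 in EMCN and 0.17 in ERG, and 0.13 in KRT7 and -0.13 in CLDN4, in the same order.

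ID1 fell from 12.04 ± 0.08 to 11.12 ± 0.13 (SD, n = 3; adjusted p = 1.02e-04, limma). The zinc finger genes ZNF57, ZNF823 and ZNF416 had log2 fold changes of -0.78 ± 0.13, -0.60 ± 0.11 and -0.51 ± 0.09 (SE). ZNF709 fell by 0.59 on the log2 scale (SE 0.10), which may be understated, since its TNF mean of 4.79 is not shown to be above background. ARRDC3 and TXNIP, both of the alpha-arrestin family, changed by -0.71 ± 0.10 and -0.53 ± 0.10. TET1, a DNA demethylation enzyme, changed by -0.62 ± 0.12, while its other probe set gave 0.26. PPP1R3D, a glycogen-targeting phosphatase subunit, changed by -0.55 ± 0.10, with -0.22 at its other probe set, and DDIT4, a stress-induced inhibitor of mTOR signalling, by -0.54 ± 0.10. The 5 probe sets of ZNF709 ran from -0.59 to 0.18. The number of lower genes changed when single arrays were left out, in fits whose smaller number of arrays also lowers the power to call a gene. It was 3 without unstimulated replicate 1, 3 without unstimulated replicate 2, 5 without unstimulated replicate 3, 6 without TNF replicate 1, and 12 without TNF replicate 2 or TNF replicate 3. ID1 was the only lower gene called in all 6 of these fits. In the fits where ARRDC3, DDIT4, PPP1R3D, TET1, TXNIP and the 4 ZNF genes lost their calls, adjusted p ran from 0.0503 to 0.274 (limma). ARRDC3 lost its call without unstimulated replicate 3 (0.0503), ZNF709 without unstimulated replicate 1 (0.12), and ZNF57 without unstimulated replicate 1 (0.154) or 2 (0.066). DDIT4 lost it without unstimulated replicate 1 (0.274) or 2 (0.117), or TNF replicate 1 (0.13) or 2 (0.0775). PPP1R3D lost it without unstimulated replicate 1 (0.274) or 2 (0.12), or TNF replicate 1 (0.0982) or 3 (0.104). ZNF823 lost it without unstimulated replicate 2 (0.0655) or 3 (0.12), or TNF replicate 1 (0.104) or 3 (0.0736). TET1 and ZNF416 were called only without TNF replicate 3 among these fits, and TXNIP only without TNF replicate 2. In the other fits their adjusted p ran from 0.0735 (TET1, without unstimulated replicate 3) to 0.208 (without unstimulated replicate 1), from 0.0655 (ZNF416, without unstimulated replicate 2) to 0.143 (without unstimulated replicate 1), and from 0.0726 (TXNIP, without TNF replicate 3) to 0.164 (without unstimulated replicate 1). Of the 102 higher genes, 67 were called in all 6 fits.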

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

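The tests of RNA quality on the called genes and of flask handling were chosen only after the results were seen. Outside the genes tested, 8 of 11721 probe sets with no gene in the table used were higher after TNF and 0 were lower (limma over all non-control probe sets, adjusted p under 0.05), with log2 fold changes of 0.58 to 2.72 and a median of 0.74. Of the 1801 probe sets that match several genes, 6 were higher and 1 was lower. These signals lie outside the genes compared, and no gene is assigned to them here.

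The ACTB 3' minus 5' difference averaged 1.52 in TNF arrays against 0.81 in unstimulated arrays, in control probe sets outside the comparison of genes. Lower RNA quality of TNF replicate 3 was set against the response to TNF as the source of the calls. The median log2 change of the 102 higher genes was 0.816 without that array and 0.828 with it, with a per-gene ratio of 1.00 (quartiles 0.974 and 1.03). The 13 lower genes had a median of -0.601 without it and -0.551 with it (per-gene ratio 1.04, quartiles 0.962 and 1.15), and 85 of the 102 and 8 of the 13 were still called on 5 arrays. With every array's ACTB difference as a covariate the medians were 0.825 and -0.613. The per-gene ratios were 1.00 (quartiles 0.962 and 1.05) and 1.06 (quartiles 0.942 and 1.19), with 78 of the 102 and 8 of the 13 still called. The changes of these genes thus did not rest on TNF replicate 3 alone. Calling them on the same arrays favours genes that changed alike in all TNF arrays, so little movement was likely in advance. The ACTB difference also separates the 2 groups, and its spread within groups comes mostly from TNF replicate 3. The covariate therefore cannot separate RNA quality that differs between the groups from TNF, and culture differences between flasks stay open.

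The 27 rises among 52 immediate-early genes, with a list mean of 0.999, are open to another reading. Genes such as FOS and EGR1 also respond to medium change and mechanical handling, so handling of the TNF flasks when TNF was added could contribute to this part. The labels name no mock-handled flasks, and no value in these data separates handling from TNF, so the 2 cannot be told apart for this list. The same limit holds for the other called genes.

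Of the 10 ways to split the 6 arrays into 3 and 3, only the real split, 1 of 10, called as many as 115 genes, and the highest count of the other splits was 0. With 10 splits the share cannot fall below 0.1, too few for a test at 0.05.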

How the results depend on the processing

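The RNA-quality covariate and the lists without called members were chosen after seeing the data. The 115 calls became 175 with trended, robust moderation (26 lower) and 14 with no moderation (14 higher, 0 lower, 12 at 1.5-fold), where 2 groups of 3 leave 4 residual degrees of freedom per gene. The other settings gave 84 to 159 calls, and leaving out single arrays gave 75 to 107, of them 70 to 102 higher and 3 to 12 lower. With the replicate block 108 genes were called (98 higher, 10 lower), 102 of them shared with the fit without it. Equal replicate numbers did not deviate together (correlations -0.044, 0.111 and 0.008), so the numbers are not taken to pair the arrays. Scaling moved the median of all genes by little (0.005 as deposited, -0.008 after quantile normalization, 0.001 after centring). No list that passed by camera changed sign in any setting. Among lists that did not pass, the means of cell cycle, stress, TNF receptor, endothelial, epithelial and leukocyte genes changed sign in at least 1 setting (leukocyte markers -0.074 with the filter on level). With an estimated correlation in camera, the lists of cytokines (mean log2 fold change 0.423), chemokines (0.346), adhesion molecules (0.171), matrix genes (0.104) and interferon response genes (-0.032) no longer passed. Directional fry lost the matrix (0.104) and interferon (-0.032) lists. Mixed fry added the subunit (0.156), TNF receptor (0.111), labour (0.105) and stress (0.005) lists. Without called members, adhesion (0.073), chemokine (0.13) and matrix genes (0.087) no longer passed. With every probe set on its own, adhesion molecules (0.038) were lost, and subunits (0.213), leukocyte markers (0.099) and hypoxia genes (-0.082) passed. Without _x_at and _s_at probe sets, subunits (0.217) and contractile genes (0.104) passed. The mean of probe sets added leukocyte markers (0.092), the filter above the median level lost matrix genes (0.096), and the covariate added subunits (0.16). Leaving out single arrays gave list means of 0.09 to 0.124 for matrix genes, -0.046 to -0.008 for interferon genes, 0.114 to 0.178 for subunits, 0.079 to 0.126 for leukocyte markers and 0.053 to 0.095 for contractile genes, each with a changed call. Over all settings and the 68 named genes, 1039 values kept their side of the threshold, 142 fell short of it and 5 newly passed (CCL2 in 3 settings, CXCL8 with trended moderation, and VLDLR with the replicate block). Of the 115 called genes 1 changed sign, EGR4, with the probe sets not ending in _x_at or _s_at. OXTR, NFKB1, TNFRSF1A, RELA and KRT7, all uncalled, did in some settings. Genes under the level filter, or with only _x_at or _s_at probe sets, have no value there. Of the 46 named genes past the threshold, 28 passed without any one array. Beyond the loss of moderation itself, the causes were not tested. The number of arrays limits what small changes can be called, and signal over background is unknown.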

Other observations

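The genes of this paragraph and ZNF670 were chosen after their values were seen, and the ZNF class was tested after 4 of its members had been seen to fall. Of the 115 called genes, 55 were in none of the fixed lists. Among them, ERRFI1, a feedback inhibitor of the EGF receptor, rose 3.43-fold (log2 fold change 1.78 ± 0.09, SE), and SPRY2, an inhibitor of receptor tyrosine kinase signalling, rose 1.74-fold (0.79 ± 0.09). The substrate adaptor gene KBTBD8 rose 3.74-fold and FAM43A 3.01-fold. RASD1, a small GTPase gene, rose 2.46-fold and TIPARP, a mono-ADP-ribosyltransferase gene, 2.12-fold. PTX3, which encodes the soluble pattern recognition molecule pentraxin 3, rose 1.96-fold, and the transcription factor genes ETS2 and MSC rose 1.87-fold and 1.88-fold. MSC missed the threshold without unstimulated replicate 3 (adjusted p = 0.0528, limma), and the other genes named so far passed without any one array. Several cytokine genes lay short of the threshold. IL11 had a log2 fold change of 0.83 ± 0.19 (adjusted p = 0.122, limma), CSF3 one of 0.55 ± 0.11 (0.0601) and IL1B one of 0.50 ± 0.11 (0.0728).

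ZNF670 rose (0.50 ± 0.09, SE), though of the 6 fits without 1 array only that without TNF replicate 2 called it (adjusted p 0.0655 to 0.0814 in the others), but the 4 ZNF genes among the 13 lower genes raise the hypothesis that zinc finger transcripts may be lower as a class after TNF. The other 497 ZNF genes, without the 5 called, had a median log2 change of -0.028, against 0.006 in other genes, and 59.4% lay below 0, against 47.6%. Of 10000 level-matched random lists 0 were as low, and camera gave p = 0.000884 with the preset correlation, but p = 0.234 with an estimated one of 0.066, so the class shift is not established. Without TNF replicate 3 the median was -0.041, and that array's own median was 0, so the lower median did not come from that array. The move from -0.028 to -0.041 is smaller than the SD of 0.037 between the unstimulated arrays' medians. It therefore does not decide whether RNA quality plays a part. The medians of single TNF arrays ran from -0.062 to 0 and the unstimulated arrays' medians had an SD of 0.037, which leaves variation between flasks open.

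For CXCL8, which did not pass the threshold, the dimmer probe set had a log2 change that differed by -0.24 (SE 0.404) from that of the brightest one, a difference within its error. This SE treats the probe sets as independent, though both were read on the same arrays, and it comes mostly from the dimmer one (SE 0.386). The comparison therefore does not decide whether signal near the top of the scale hid a rise.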
